A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

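Nascent RNA bound to RNA polymerase II was sequenced in 8 yeast libraries: 2 biological replicates each, per the labels, of wild type and of the cac1, cac2 and cac3 mutants. Each library came as a table of ORF-T and other features and a table of noncoding features. Read counts over each feature were deposited by the authors as whole numbers, per the file headers the span of the feature. A second estimated count, of reads in a window beside each feature's 5′ end, was deposited with empty windows entered as 0.5 by the authors, in 1 to 126 ORF-T-table windows per library. The ratio of the feature count to the window count was deposited by the authors, as was an RPKM of each that rested on the total of the ORF-T table's feature and window reads. In the noncoding table the deposited RPKM was a millionth of that scale and was not used. Natural log values in the mutant tables were deposited by the authors and equalled the log of the mutant ratio over the wild-type ratio of the same replicate number, recomputed within 1e-06. Nascent RNA was prepared by a published NET-seq protocol, per the labels; the genome build, aligner and read filters are not given in the sources used here.

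All levels and tests were computed from the deposited counts. There were 5498 features in the ORF-T table and 1774 in the noncoding one, on 16 chromosomes. Of these 2 ORF-Ts lay in the noncoding table, 25 gene symbols stood on more than 1 feature, and 60 of the other features were named as small nucleolar or small nuclear RNAs. Reads counted per library ran from 1880299 to 7705151, and features without a read from 4 to 40. The window was taken to run from 500 bp upstream to 100 bp downstream of the 5′ end on the opposite strand, at most 600 bp wide (1553 at full width) and otherwise shortened. Its strand was inferred: window reads ranked with reads expected from annotated features on the opposite strand (Spearman 0.14) and not with those on the same strand (-0.12), and over 659 windows with many expected reads the median ratio to the expected count was 1.31. Whether the authors' counting shared reads between overlapping features or between near-identical copies is not given in the sources used here, so values of multigene families are uncertain.

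Features with an RPKM of at least 1 in at least 2 libraries were tested: 7271 features, and 5165 ORF-T-table windows in a fit of their own with 0.5 entered as 0. Libraries were scaled by the trimmed mean of M-values over ORF-Ts (factors 0.962 to 1.02). All 8 libraries entered 1 edgeR 4.0.16 quasi-likelihood fit with a coefficient per group and no block, run in R 4.3.3, with Benjamini-Hochberg adjustment over the features of each comparison and a threshold of 0.05. Comparisons were each mutant with wild type, the mean of the 3 mutants with wild type, and each pair of mutants. The biological coefficient of variation was 8.13% (common dispersion 0.00661, prior degrees of freedom 6.7, residual degrees of freedom 4). Per-library log2 levels used a pseudocount of 1. Gene lists and classes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated, adjusted over the lists by Benjamini-Hochberg. Values per library were compared by exact permutation of the 28 splits of 2 against 6 libraries, where the smallest p is 0.036. Chance in the overlap between mutants was simulated with unchanged groups that shared simulated controls, and list medians were ranked among 10000 random lists matched on level. Ratios with few reads carry exact 95% intervals for counting error alone, with a floor of 3 reads for 0. Tables were built with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

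CUTs and SUTs were called divergent when their 5′ end lay within 500 bp of that of an ORF-T on the other strand (858), antisense when at least 50% overlapped an ORF-T on the other strand (472), and other (442). Subtelomeric ORF-Ts lay within 20 kb of the largest feature end on their chromosome, which stood in for the chromosome end. The 31 gene lists held CAF-I subunits, histones, other histone chaperones, silencing and remodelling factors, silent mating loci and MAT, a-specific, alpha-specific, pheromone-response, meiosis, strain-marker, DNA damage, G1/S, G2/M, stress, phosphate, galactose, hexose transporter, glycolysis, respiration, ribosome biogenesis, cytosolic and mitochondrial ribosomal protein, amino acid, sulfur, iron, purine and nucleotide, ergosterol, subtelomeric family, cell wall, RNA surveillance and RNA polymerase II genes. Genes named were the 10 ORF-Ts rising most and 10 falling most, and 6 rising and 4 falling CUTs or SUTs, in the mean of the 3 mutants. For a single mutant they were 5 ORF-Ts and 3 CUTs or SUTs each way, and between mutants 3 features each way. Each was past the threshold, had a mean RPKM of at least 5 and had its mutant libraries all on one side of both controls. Deleted genes, PPT1 and SUT129, and up to 4 list members past the threshold (or the 2 of highest level) were added. Comparisons, lists, the naming rule and the alternatives were chosen before the data were examined, except where the text says otherwise.

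The alternatives were no further scaling, scaling over all features, DESeq2 1.42.0, no filter or a mean RPKM of at least 5, the replicate number as a block, only the groups compared, and each library left out in turn. Comparisons of 2 mutants with separate wild-type libraries were added after the data were seen. Classes also had ORF-Ts matched on level, and other distances of 300 and 1000 bp or of 10 and 40 kb. A group left with 1 library was assumed to vary like the other groups. Replicate numbers paired the samples: deviations of same-numbered libraries from their group means correlated in each of the 6 pairs of groups (0.368 to 0.544 over 6199 features), and the second principal component, with 18.6% of the variance, separated the numbers. The authors' log values pair the same numbers, and the labels do not say what a number shares. Pearson correlations of log2 levels were 0.974 to 0.990 within groups and 0.954 to 0.989 between groups, and replicates differed by more than counting error in each group (chi-square per feature 4.02 to 6.88). On simulated counts with this spread, the comparison of cac1 with wild type recovered 70%, 96% and 100% of 50 features each changed 1.5-fold, 2-fold and 4-fold, with 9 calls among 7071 unchanged features (5.96% of its calls). The mean of the 3 mutants recovered 84%, 94% and 100%, with 14 such calls (8.54%). Of 50 features changed by 25% only 18% and 22% were recovered, so most small changes were missed. Camera called 0 of 20 unchanged simulated sets at unadjusted p under 0.05 and a changed set of 30 at 1.62e-40. Correlated sets were untested.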

Results

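Nascent transcription was measured in budding yeast by native elongating transcript sequencing (NET-seq), in which RNA still bound to RNA polymerase II is purified through a tagged Rpb3 subunit and sequenced. The 8 libraries came from cells in mid-log growth in rich glucose medium. They fell into 4 groups of 2 biological replicates each: wild type and the cac1, cac2 and cac3 mutants. CAC1, CAC2 and CAC3 encode the subunits of chromatin assembly factor I (CAF-I), the histone chaperone that deposits histones H3 and H4 on newly replicated DNA. The labels give the wild type a strain name of another series than the mutants, so strain background and the comparison of wild type with mutants cannot be told apart. Reads were counted by the authors on 5171 open-reading-frame transcripts (ORF-Ts), 925 cryptic unstable transcripts (CUTs), 847 stable unannotated transcripts (SUTs) and 329 other features. Reads counted per library were 1880299 and 7705151 in wild type, 1959549 and 4679697 in cac1, 2275416 and 3720649 in cac2, and 7117979 and 6604240 in cac3. CUTs and SUTs together held between 6.44% and 6.97% of the reads of each library. Levels are in RPKM (read density per kilobase of feature, scaled between libraries), as mean ± SD over 2 libraries. Changes are log2 differences from wild type with their standard error (SE), and "rose" and "fell" are used only for an adjusted p below 0.05 by the edgeR quasi-likelihood test.

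The deleted genes were examined first. RLF2, the gene for Cac1 (YPR018W, chromosome XVI, 594355 to 596379), fell from 38.3 ± 1.04 in wild type to 13.8 ± 0.379 in cac1, and stood at 37.2 ± 0.813 in cac2 and 38.3 ± 1.66 in cac3. CAC2 (YML102W, chromosome XIII, 68265 to 69753) fell from 61.1 ± 5.66 to 19.9 ± 0.453 in cac2, beside 72.7 ± 5.23 in cac1 and 62.2 ± 3.39 in cac3. MSI1, the gene for Cac3 (YBR195C, chromosome II, 610492 to 611916), fell from 72.1 ± 1.90 to 32.2 ± 3.10 in cac3, beside 77.7 ± 0.0533 in cac1 and 78.0 ± 0.832 in cac2. The log2 changes in the gene's own mutant were -1.47 (SE 0.10, edgeR adjusted p = 1.2e-05) for RLF2, -1.59 (SE 0.11, adjusted p = 1.32e-05) for CAC2 and -1.17 (SE 0.07, adjusted p = 1.42e-05) for MSI1. Reads remained on each deleted gene: 57 and 131 on RLF2 in the cac1 libraries, 67 and 113 on CAC2 in cac2, and 350 and 278 on MSI1 in cac3. Whether the counted features reach beyond the deleted parts is not given in the sources used here, so the remaining reads do not measure transcription of a deleted gene.

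**Figure D1:**
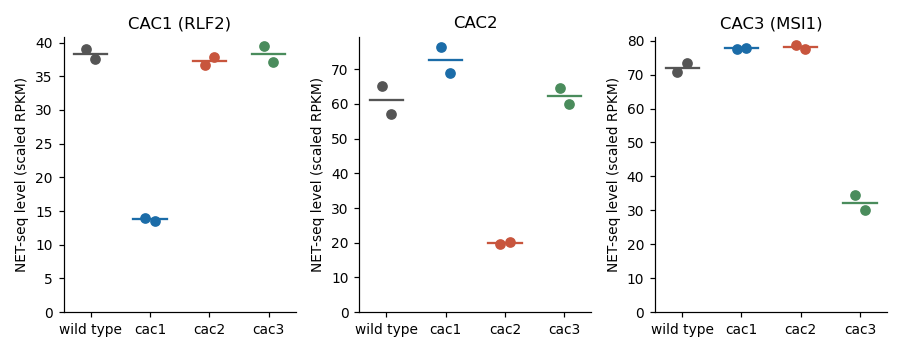
Level of the 3 CAF-I genes in each library (points, scaled RPKM) with group means (lines). Each gene was lowest in its own mutant, with means of 13.8 for RLF2 in cac1, 19.9 for CAC2 in cac2 and 32.2 for MSI1 in cac3.

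Averaged over the 3 mutants, the largest rises were on genes of low level in wild type. STE3, the a-factor receptor of alpha cells (YKL178C, chromosome XI, 112896 to 114888), rose from 2.45 ± 0.785 to 17.9 ± 1.60 in cac1, 20.6 ± 2.22 in cac2 and 14.6 ± 0.750 in cac3, a mean log2 change of 3.01 (SE 0.19, edgeR adjusted p = 8.89e-06). YHL012W (chromosome VIII, 79690 to 80522) rose from 5.14 ± 1.99 to 34.0 ± 0.992, 41.03 ± 0.227 and 25.4 ± 2.18 in the same order, a mean of 2.90 (SE 0.20). Here and below, features rising or falling most are those of the naming rule (mean RPKM of at least 5). The others rising most were YNR064C (3.08, SE 0.35) and CAT2 (2.86, SE 0.36, on 1 of its 2 features). Next came YSW1 (2.54, SE 0.24) and SPS19 (2.43, SE 0.38). They were followed by YNR062C (2.41, SE 0.38), PES4 (2.40, SE 0.38), and PDC6 for a minor pyruvate decarboxylase (2.37, SE 0.44). MF(ALPHA)2, which encodes alpha-factor, rose as well, but with 3 wild-type reads against 44 in the mutants its pooled ratio was 5.12 with an exact 95% counting interval of 1.64 to 25.8.

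The largest falls were smaller than the largest rises. RIB4, which encodes lumazine synthase of riboflavin synthesis (YOL143C, chromosome XV, 54542 to 55350), fell from 415 ± 27.3 to 201 ± 15.8, 187 ± 2.28 and 306 ± 10.8, a mean of -0.87 (SE 0.07, edgeR adjusted p = 2.77e-05). URA1, the dihydroorotate dehydrogenase of pyrimidine synthesis (YKL216W, chromosome XI, 25145 to 26457), fell from 820 ± 0.841 to 404 ± 41.7, 382 ± 7.05 and 669 ± 4.38, a mean of -0.80 (SE 0.05). MDH2 fell by 0.78 (SE 0.04), CLB1 by 0.73 (SE 0.06) and the Pho85 cyclin gene PCL5 by 0.69 (SE 0.06). IME1, the master activator of meiosis, fell by 0.92 (SE 0.16) and the spore-formation gene SSP1 by 0.87 (SE 0.21). RPI1 (-0.77, SE 0.08), YDR379C-A (-0.66, SE 0.18) and YGP1 (-0.64, SE 0.09) completed the 10 ORF-Ts falling most by the naming rule. That rule left out PHO84, which fell more.

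**Figure D2:**
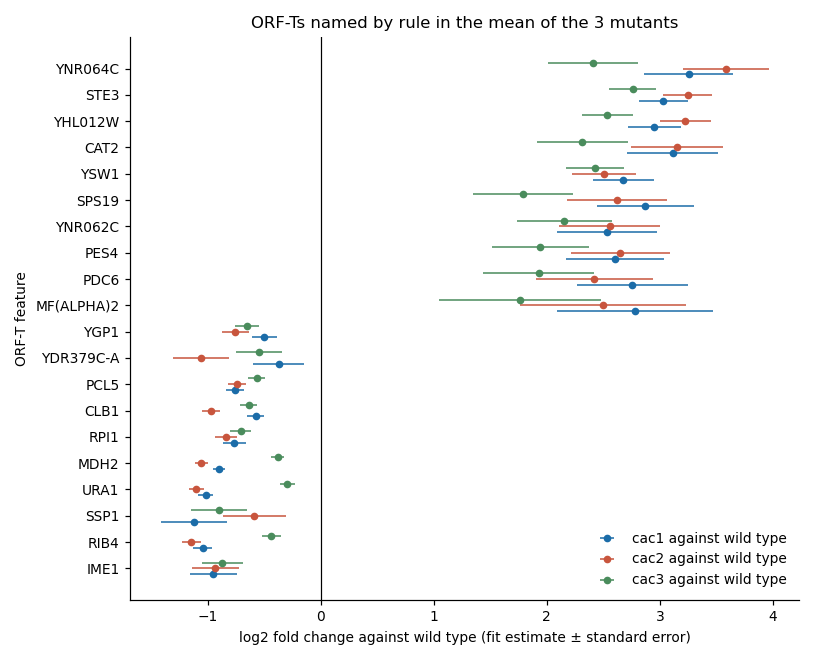
Log2 fold change against wild type of the ORF-Ts named by rule as rising or falling most in the mean of the 3 mutants, 10 each. Each mutant has 1 point and standard error. STE3 stood at 3.03, 3.25 and 2.76 in cac1, cac2 and cac3, and URA1 at -1.02, -1.10 and -0.29.

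Genes of ribosomes, amino acid synthesis, glycolysis and histones had negative medians in the mean of the 3 mutants. Of 131 cytosolic ribosomal protein genes 79 fell and 1 rose (1 higher and 102 lower adjusted over the list alone), with a median of -0.18. RPS14B (-0.43), RPL36A (-0.37), RPS9A (-0.37) and RPL26B (-0.34) were examples, and the camera set test gave an adjusted p = 3.32e-17. With the correlation estimated in place of preset, no list of the mean of the 3 mutants passed, the smallest camera adjusted p being 0.212. Of 66 mitochondrial ribosomal protein genes 10 fell and none rose (0 and 10 over the list alone), by a median of -0.13, with MRPL44 at -0.62 and MRPL51 at -0.37 (camera adjusted p = 4.97e-06). Amino acid biosynthesis genes, the targets of Gcn4, had 17 of 37 members lower and 0 higher (0 and 17 over the list alone), such as ARG1 (-0.52), ARG4 (-0.35), ASN1 (-0.34) and HIS4 (-0.34). Their median was -0.19 (camera adjusted p = 3.89e-06). Among 17 glycolysis and fermentation genes 11 fell, with ENO1 at -0.61, TDH2 at -0.55 and PGK1 at -0.24, while PDC5 rose by 0.77 (1 higher and 13 lower over the list alone, median -0.16, camera adjusted p = 0.000487). Histone genes fell in 6 of 11 cases, none rising, with HTZ1, the gene of the variant H2A.Z, at -0.45, HTB2 at -0.45 and HTA2 at -0.40 (0 and 11 over the list alone, median -0.22, camera adjusted p = 1.35e-05). All 3 CAF-I subunit genes fell (3 over the list alone), each by its deletion in 1 mutant, so their median of -0.42 is no independent result (camera adjusted p = 0.000469). Ranked, after the data were seen, among 10000 random ORF-T lists matched on level, the median of the ribosomal protein genes lay at percentile 0.01 (random median -0.13) and that of the histone genes at 0.55 (random median -0.12), though at 10.9 without wild-type replicate 1. The glycolysis median lay at percentile 25.4, within what such lists gave (random median -0.14). Without further scaling of the libraries the falls were 40 cytosolic and 6 mitochondrial ribosomal protein genes and 6 glycolysis genes, with medians of -0.12, -0.07 and -0.10, and with replicate as a block 10 histone genes fell. The falls were, without wild-type replicate 2, 10 cytosolic and 2 mitochondrial ribosomal protein, 3 amino acid (median -0.12), 2 glycolysis and 2 histone genes. They were, without wild-type replicate 1, 40 cytosolic and 3 mitochondrial ribosomal protein, 6 glycolysis and 3 histone genes, and without cac3 replicate 1, 50 cytosolic and 6 mitochondrial ones of the ribosome.

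Stress, sporulation, DNA damage, galactose, alpha-cell, subtelomeric and iron genes had positive medians and passed the camera test with its preset correlation. Of 23 heat shock and general stress genes 12 rose and 0 fell (14 and 0 adjusted over the list alone). Examples were GSY1 (1.11), CTT1 (0.80), SPI1 (0.77), SSA4 (0.67) and HSP82 (0.61). The list's median was 0.35 (camera adjusted p = 1.95e-06). Among 11 meiosis and sporulation genes 6 rose and IME1 alone fell (6 and 1 over the list alone). DMC1 rose by 1.79, DIT1 by 1.74, SPR3 by 1.67 and REC8 by 1.60 (median 0.49, camera adjusted p = 0.000512). Of 12 DNA damage and replication stress genes 6 rose and 1 fell (9 and 1 over the list alone). MAG1 stood at 0.67, RNR2 at 0.37, RNR4 at 0.35 and RAD54 at 0.30. The falling member was RNR1 at -0.18 (median 0.29, camera adjusted p = 0.00133). Of 5 galactose genes GAL2 (1.68), GAL4 (0.91) and GAL3 (0.88) rose, with 4 higher over the list alone (median 0.88, camera adjusted p = 0.00295). Of 5 alpha-cell-specific genes STE3, MF(ALPHA)2 and YLR040C (0.42) rose, with 4 higher over the list alone, and SAG1, the alpha-agglutinin gene, stood at -0.01. The list's median of 2.20 was the fitted value of MF(ALPHA)1, which had 2 wild-type reads against 29 and a pooled ratio of 5.06 (exact 95% counting interval 1.28 to 43.8). Camera gave this list an adjusted p = 0.00338; without wild-type replicate 2 the median was 0.38 and the adjusted p = 0.0814. Of 15 subtelomeric multigene family members 5 rose (5 over the list alone), with SEO1 at 1.253, COS12 at 1.01, COS111 at 0.53 and TIR1 at 0.52 (median 0.17, camera adjusted p = 0.00755, and adjusted p = 0.067 with replicate as a block). Of 15 iron regulon genes 4 rose (4 over the list alone), namely the siderophore transporter gene SIT1 (0.84), the ferroxidase gene FET3 (0.57), CCC2 (0.37) and FTR1 (0.23; median 0.15). Camera gave it an adjusted p = 0.0165, and adjusted p = 0.105 without wild-type replicate 2, where the median was 0.05. Among random lists matched on level the stress median lay at percentile 99.99, DNA damage at 99.93 and the alpha-cell genes at 100, but the last at 59.9 without wild-type replicate 2. Meiosis and sporulation genes lay at percentile 37.2 (random median 0.57), galactose genes at 76.6 (0.57), subtelomeric families at 67.9 (0.13) and iron genes at 94.8 (0.04), within the middle 95% of such lists. Rises numbered 3 stress, 1 meiosis, 1 DNA damage, 1 alpha-specific, 1 subtelomeric, 1 iron and 0 galactose genes without wild-type replicate 2, and without wild-type replicate 1, 7 stress genes.

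The remaining lists did not pass camera in the mean of the 3 mutants. By limma's fry test G1/S (adjusted p = 0.000263), pheromone, polymerase, respiration and ergosterol genes (up to 0.0433) passed. In the phosphate list 3 of 14 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.608). PHM6 stood at 1.28, PHM7 at 1.16, PHO5 at 0.71 and PHO84 at -1.21. Of 12 haploid and pheromone-response genes 3 rose and 1 fell (4 and 1, adjusted p = 0.253). PRM2 stood at 2.19, AGA1 at 0.99, KAR4 at 0.25 and GPA1 at -0.37. Of 6 a-cell-specific genes the alpha-factor receptor gene STE2 fell by 0.27 (0 and 1; adjusted p = 0.369). Respiration and tricarboxylic acid cycle genes gave 6 rises and 8 falls of 35 (7 and 10; adjusted p = 0.234), from CIT3 at 1.45 and SDH1 at 0.41 to COX7 at -0.37 and QCR10 at -0.36. G1/S genes gave 0 and 4 of 19 (0 and 4; adjusted p = 0.253), with CLN1 at -0.39, CLB6 at -0.36 and MCD1 at -0.27. G2/M genes gave 0 and 3 of 16 (0 and 2; adjusted p = 0.369), with CLB1, CLB2 at -0.29 and SWI5 at -0.19. Purine and nucleotide genes gave 4 and 3 of 15 (6 and 3; adjusted p = 0.76), with ADE17 at 0.51 and SHM2 at 0.48 beside URA1 and URA4 at -0.59. Sulfur and methionine genes gave 3 and 1 of 19 (3 and 1; adjusted p = 0.354), with MET16 at 0.62 and MUP1 at -0.30. Hexose transporter genes gave 2 and 1 of 8 (3 and 1; adjusted p = 0.76), with HXT2 at 0.36, HXT1 at 0.28 and HXT3 at -0.54. Cell wall and adhesion genes gave 3 and 3 of 20 (3 and 3; adjusted p = 0.732), with CWP1 at 0.56 and TIP1 at -0.27. Nuclear RNA surveillance and termination genes gave 1 and 2 of 16 (2 and 3; adjusted p = 0.58), with RAT1 at 0.22 and SSU72 at -0.32. Silencing and remodelling factors gave 1 and 1 of 22 (1 and 1; adjusted p = 0.732), with SIR2 at 0.28 and RSC2 at -0.24. Strain-marker genes gave 1 and 1 of 9 (1 and 1; adjusted p = 0.76), with ADE2 at 0.30 and LYS2 at -0.21. Ribosome biogenesis genes gave 1 and 1 of 44 (1 and 0; adjusted p = 0.661), with DBP2 at 0.20 and SIK1 at -0.14. Ergosterol genes gave 2 and 0 of 20 (0 and 0; adjusted p = 0.725), with ERG8 at 0.27 and ERG13 at 0.21. Of 12 other histone chaperones the centromeric chaperone gene SCM3 rose by 0.41 (0 and 0; adjusted p = 0.827), and the list had a median of -0.005 and a mean of 0.010 with a test pointing down. Of 21 genes for RNA polymerase II subunits and elongation factors none passed (0 and 0; adjusted p = 0.222), RPB10 being at -0.10 and SPT4 at -0.15. Only 1 of the 7 genes at the silent mating loci and MAT was measured: HMRA1 fell by 0.48 (SE 0.12).

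In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 7271 features, 549 ORF-Ts rose and 471 fell, and 263 CUTs and SUTs rose and 177 fell. Without further scaling of the libraries the balance of the ORF-Ts moved from 53.8% to 78.0% higher (828 and 233), and that of the CUTs and SUTs from 59.8% to 72.2% higher (337 and 130). With replicate as a block 721 ORF-Ts fell. Wild-type replicate 2, the deeper of the pair, decided many calls: without it 75 ORF-Ts rose and 61 fell, with 29 and 23 CUTs and SUTs. Of the 30 features named by rule 17 then no longer passed, PDC6 standing at 1.28, SPS19 at 1.254, PES4 at 1.23 and YNR062C at 1.60. Without wild-type replicate 1 the numbers were 323 and 206 ORF-Ts with 156 and 116 CUTs and SUTs; without cac3 replicate 1 the falls were 278 ORF-Ts, and without cac3 replicate 2 they were 306.

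**Figure D3:**
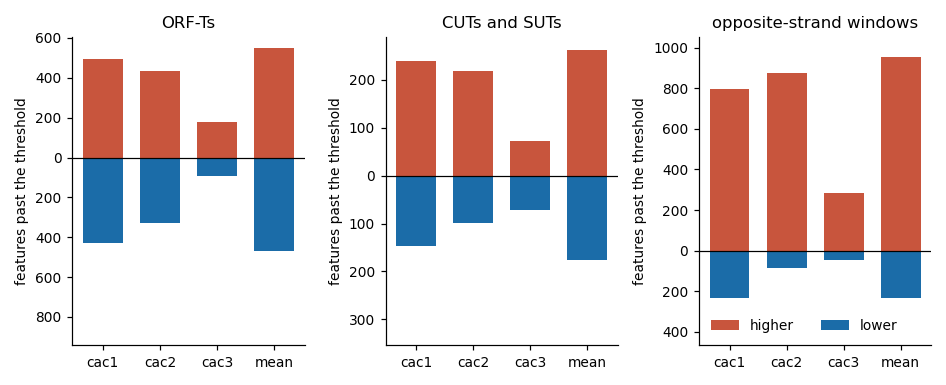
Number of features past the threshold (adjusted p below 0.05) against wild type, counted upwards for higher and downwards for lower, for each mutant and the mean of the 3. The mean of the 3 mutants had 549 higher and 471 lower ORF-Ts, 263 and 177 CUTs and SUTs, and 956 and 233 windows on the opposite strand.

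In the cac1 mutant alone, YNR064C (3.25, SE 0.39), CAT2 (3.12, SE 0.40, on 1 of its 2 features), STE3 (3.03, SE 0.22), YHL012W (2.95, SE 0.23) and SPS19 (2.87, SE 0.43) rose most among ORF-Ts. Besides the deleted RLF2, PHO84, the high-affinity phosphate transporter (YML123C, chromosome XIII, 23941 to 25853), fell from 107 ± 6.14 to 24.2 ± 3.94, a log2 change of -2.11 (SE 0.10, edgeR adjusted p = 1.21e-06). SSP1 fell by 1.12 (SE 0.29), RIB4 by 1.04 (SE 0.08) and URA1 by 1.02 (SE 0.07). Among noncoding transcripts SUT041 (-2.36, SE 0.36), CUT743 (-2.20, SE 0.45) and CUT268 (-1.38, SE 0.18) fell. SUT649 rose with 2 wild-type reads against 73 in the 3 mutants (pooled ratio 12.7, exact 95% counting interval 3.40 to 107) and SUT561 with 2 against 37 (6.45, interval 1.66 to 55.3). SUT450 had no wild-type read and 12 in the mutants, and the exact 95% interval of its pooled ratio started at 0.969, so no change was not excluded by counting alone.

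Ribosomal protein genes were the list with the most genes changed in cac1: 79.4% of 131 fell and 0 rose (0 and 119 adjusted over the list alone), with RPS9A at -0.52, RPL36A at -0.50 and RPL26B at -0.49 (median -0.28, camera adjusted p = 4.39e-28). With an estimated correlation the smallest camera adjusted p of a list in cac1 was 0.0833. Of 11 histone genes 8 fell (0 and 9 over the list alone), led by HTB2 at -0.71, HTA2 at -0.61, HTZ1 at -0.47 and HHF2 at -0.46 (median -0.33, adjusted p = 2.24e-06). Stress genes gave 13 rises and 0 falls of 23 (15 and 0), with GSY1 at 1.33, SSA4 at 0.92 and CTT1 at 0.82 (median 0.49, adjusted p = 7.45e-10). Of 5 galactose genes GAL2 (2.03), GAL4 (1.06), GAL3 (0.98) and GAL80 (0.26) rose (4 and 0; median 0.98, adjusted p = 0.000767). DNA damage genes gave 6 and 1 of 12 (9 and 1; median 0.41, adjusted p = 0.000592) and meiosis genes 5 and 1 of 11 (5 and 1; median 0.69, adjusted p = 0.000539). Amino acid genes gave 0 and 13 of 37 (1 and 15; median -0.11, adjusted p = 0.00152). Glycolysis genes gave 0 and 10 of 17 (1 and 10; median -0.16, adjusted p = 0.00163). Mitochondrial ribosomal protein genes gave 0 and 8 of 66 (0 and 7; median -0.15, adjusted p = 4.48e-05). Alpha-specific genes gave 2 and 0 of 5 (3 and 0; adjusted p = 0.00322, and adjusted p = 0.0523 without wild-type replicate 2). Subtelomeric families gave 4 and 0 of 15 (5 and 0; median 0.27, adjusted p = 0.00872, and adjusted p = 0.0568 with replicate as a block). Sulfur genes gave 4 and 1 of 19 (4 and 1), with MET16 at 0.75, MET2 at 0.48 and MUP1 at -0.26 (median 0.21, adjusted p = 0.0432). The sulfur call was lost with replicate as a block (adjusted p = 0.119), without wild-type replicate 1 (0.111) and without cac1 replicate 1 (0.238). The CAF-I list, with 1 deleted member, had a median of 0.10, a mean of -0.37 and a test pointing down (adjusted p = 0.389). Among random lists matched on level glycolysis lay at percentile 70.0 in cac1, amino acid genes at 15.1, meiosis genes at 48.8, galactose genes at 72.7 and subtelomeric families at 81.6, all within the middle 95%. Without further scaling 5 amino acid, 4 glycolysis and 3 mitochondrial ribosomal protein genes fell (medians -0.03, -0.08 and -0.07) and 7 sulfur genes rose, and with replicate as a block 14 mitochondrial ribosomal protein genes fell. In cac1 24 ribosomal protein, 4 histone, 2 glycolysis, 1 amino acid and 1 mitochondrial ribosomal protein genes fell without wild-type replicate 2. The rises were then 6 stress, 2 DNA damage and 1 each of galactose, meiosis, alpha-specific (median 0.79), subtelomeric and sulfur genes. Falls of 5 amino acid, 6 glycolysis and 3 mitochondrial ribosomal protein genes and rises of 2 sulfur genes (median 0.12) were left without wild-type replicate 1. Without cac1 replicate 1, 67 cytosolic and 4 mitochondrial ribosomal protein, 8 amino acid and 6 glycolysis genes fell and 1 sulfur gene rose (median 0.13). Without cac1 replicate 2, 6 amino acid, 6 glycolysis and 2 mitochondrial ribosomal protein genes fell, and 8 stress, 2 sulfur and 1 subtelomeric genes rose. The subtelomeric median was 0.18 without the first and 0.43 without the second.

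In total 495 ORF-Ts rose and 427 fell in cac1 by the edgeR quasi-likelihood test, and 240 CUTs and SUTs rose and 147 fell. With replicate as a block the numbers were 748 and 647 ORF-Ts with 348 and 226 CUTs and SUTs, and without further scaling 846 and 198 ORF-Ts (81.0% against 53.7% higher) with 322 and 101 CUTs and SUTs (76.1% against 62.0%). Without wild-type replicate 2 there were 103 and 66 ORF-Ts with 32 and 23 CUTs and SUTs, and without wild-type replicate 1, 345 and 239 with 160 and 107. Without cac1 replicate 1 there were 312 and 216 with 159 and 81, and without cac1 replicate 2, 373 and 332 with 118 and 91.

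In the cac2 mutant the ORF-Ts rising most were YNR064C (3.58, SE 0.38), STE3 (3.25, SE 0.21), YHL012W (3.23, SE 0.23), CAT2 (3.15, SE 0.41, on 1 of its 2 features) and PES4 (2.65, SE 0.44). Besides CAC2 itself, PHO84 fell to 30.4 ± 0.990 (-1.81, SE 0.10, edgeR adjusted p = 3.68e-06), RIB4 by 1.15 (SE 0.08), URA1 by 1.10 (SE 0.07) and YDR379C-A by 1.06 (SE 0.25). FRE7, a putative metal reductase gene (YOL152W, chromosome XV, 40705 to 42690), rose from 42.1 ± 0.604 to 104.4 ± 8.63 (1.31, SE 0.09). Of noncoding transcripts SUT364, a SUT divergent from DBP5, rose by 3.17 (SE 0.61), beside SUT450 and SUT649, and SUT041 (-2.20, SE 0.36), CUT683 (-1.44, SE 0.26) and CUT268 (-1.39, SE 0.18) fell most.

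Ribosomal protein genes gave 1 rise and 43 falls of 131 in cac2 (1 and 62 adjusted over the list alone), with RPS14B at -0.48, RPL8A at -0.39 and RPL36A at -0.37 (median -0.16, camera adjusted p = 4.62e-12). With an estimated correlation the smallest camera adjusted p in cac2 was 0.263. Glycolysis genes gave 0 and 13 of 17 (1 and 14), with ENO1 at -0.72, TDH2 at -0.54 and PGK1 at -0.32 (median -0.22, adjusted p = 4.28e-05). Amino acid genes gave 0 and 13 of 37 (0 and 18), with ARG1 at -0.53, ASN1 at -0.43 and BAT2 at -0.40 (median -0.18, adjusted p = 1.92e-05). Histone genes gave 0 and 5 of 11 (0 and 8), with HTZ1 at -0.51 and HTB2 at -0.44 (median -0.27, adjusted p = 0.000106). Mitochondrial ribosomal protein genes gave 0 and 4 of 66 (0 and 4), with MRPL44 at -0.73 (median -0.13, adjusted p = 0.000106). Stress genes gave 8 and 0 of 23 (10 and 0), with GSY1 at 1.27 and CTT1 at 0.92 (median 0.35, adjusted p = 0.000205). Meiosis genes gave 6 and 1 of 11 (6 and 1), with REC8 at 1.87 and SPR3 at 1.82 (median 0.67, adjusted p = 0.000453). Galactose genes gave 3 and 0 of 5 (3 and 0; median 0.93, adjusted p = 0.00497) and DNA damage genes 6 and 1 of 12 (6 and 1; median 0.30, adjusted p = 0.00543). Alpha-specific genes gave 3 and 0 of 5 (3 and 0; adjusted p = 0.00308, and adjusted p = 0.0533 without wild-type replicate 2). Subtelomeric families gave 5 and 0 of 15 (6 and 0), with COS12 at 1.06 (median 0.30, adjusted p = 0.00469, 0.0504 with replicate as a block and 0.0578 without cac2 replicate 1). Iron genes gave 3 and 0 of 15 (3 and 0), with SIT1 at 0.73, the ferric reductase gene FRE1 at 0.47 and FET3 at 0.44 (median 0.16, adjusted p = 0.0257, 0.124 without wild-type replicate 2 and 0.197 without cac2 replicate 1). Among random lists matched on level the ribosomal protein genes lay at percentile 5.12 in cac2 (random median -0.12), meiosis genes at 59.2, galactose genes at 77.1, subtelomeric families at 93.1 and iron genes at 93.3, within the middle 95%. Without further scaling 20 ribosomal protein and 8 glycolysis genes fell, with medians of -0.10 for the former, -0.11 for amino acid and -0.06 for mitochondrial ribosomal protein genes, and with replicate as a block 74 cytosolic and 7 mitochondrial ones fell. The CAF-I list then had an adjusted p = 0.0114 (camera; 0.0752 without the block). In cac2 6 ribosomal protein, 4 amino acid, 2 glycolysis, 2 histone and 1 mitochondrial ribosomal protein genes fell without wild-type replicate 2. The rises were then 2 stress and 1 each of meiosis, alpha-specific (median 0.52), subtelomeric and iron genes, and 0 galactose and DNA damage genes. Falls of 22 cytosolic and 1 mitochondrial ribosomal protein genes and rises of 4 stress, 3 DNA damage, 3 subtelomeric and 1 alpha-specific genes came without wild-type replicate 1. Without cac2 replicate 1, 26 cytosolic and 2 mitochondrial ribosomal protein genes fell, and 5 stress, 2 DNA damage, 3 subtelomeric and 1 alpha-specific genes rose. Without cac2 replicate 2, 17 cytosolic and 9 mitochondrial ribosomal protein, 8 glycolysis, 6 amino acid and 3 histone genes fell. There 4 stress, 3 meiosis, 2 DNA damage, 2 subtelomeric and 1 alpha-specific genes rose, and the iron median was 0.27.

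In total 432 ORF-Ts rose and 327 fell in cac2 by edgeR, and 219 CUTs and SUTs rose and 98 fell. With replicate as a block there were 647 and 567 ORF-Ts with 336 and 162 CUTs and SUTs, and without further scaling 675 and 180 ORF-Ts (78.9% against 56.9% higher) with 294 and 72 CUTs and SUTs (80.3% against 69.1%). Without wild-type replicate 2 there were 90 and 56 ORF-Ts with 32 and 19 CUTs and SUTs, and without wild-type replicate 1, 280 and 169 with 138 and 58. Without cac2 replicate 1 there were 261 and 191 with 130 and 45, and without cac2 replicate 2, 243 and 151 with 98 and 52.

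In the cac3 mutant STE3 (2.76, SE 0.21), YHL012W (2.54, SE 0.23), YSW1 (2.43, SE 0.26), YNR064C (2.41, SE 0.40) and CAT2 (2.31, SE 0.40, on 1 of its 2 features) rose most. FRE7 fell to 14.6 ± 0.0297 (-1.53, SE 0.10, edgeR adjusted p = 1.42e-05), IME1 by 0.87 (SE 0.18), RPI1 by 0.71 (SE 0.10) and WSC4 by 0.68 (SE 0.09), besides the deleted MSI1. PHO84 stood at 132 ± 1.32, above wild type but not past the threshold (0.30, adjusted p = 0.065). SUT801 rose by 2.22 (SE 0.28) and SUT831 by 1.85 (SE 0.46), beside SUT649, and SUT041 (-1.70, SE 0.29), CUT014 divergent from QDR3 (-1.10, SE 0.12) and CUT556 divergent from FCY21 (-1.07, SE 0.28) fell.

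Amino acid genes gave 0 rises and 10 falls of 37 in cac3 (1 and 14 adjusted over the list alone), with ARG1 at -0.66, HIS4 at -0.56, ARG4 at -0.41 and ASN1 at -0.39 (median -0.14, camera adjusted p = 4.96e-08). With an estimated correlation the smallest camera adjusted p in cac3 was 0.275. Iron genes gave 4 and 1 of 15 (6 and 1), with SIT1 at 1.32, FET3 at 1.06, CCC2 at 0.41 and FTR1 at 0.33 but FRE1 at -0.60 (median 0.21, adjusted p = 0.000831). Phosphate genes gave 3 and 0 of 14 (5 and 0), with PHM6 at 1.34, PHM7 at 0.88 and PHO5 at 0.72 (median 0.27, adjusted p = 2.38e-05). Stress genes gave 5 and 0 of 23 (7 and 0; GSY1 at 0.75, median 0.18, adjusted p = 0.000336). Ribosomal protein genes gave 0 and 5 of 131 (0 and 4), with RPS14B at -0.33 (median -0.08, adjusted p = 2.38e-05). Mitochondrial ones gave 1 and 2 of 66 (1 and 2), with RSM22 at 0.29 and MRPL44 at -0.50 (median -0.13, adjusted p = 4.22e-06). Histone genes gave 0 and 1 of 11 (0 and 1), HTZ1 at -0.38 (median -0.15, adjusted p = 0.00421). Purine and nucleotide genes gave 0 and 2 of 15 (0 and 4), URA4 at -0.36 and URA1 at -0.29 (median -0.09, adjusted p = 0.0154, and 0.0843 without cac3 replicate 1). Meiosis genes gave 5 and 1 of 11 (5 and 1; median 0.38, adjusted p = 0.00271, and 0.0806 without wild-type replicate 2). Galactose genes gave 2 and 0 of 5 (3 and 0; median 0.58, adjusted p = 0.0154, and 0.147 without wild-type replicate 2). Alpha-specific genes gave 1 and 0 of 5 (2 and 0; adjusted p = 0.00285, and 0.149 without wild-type replicate 2). DNA damage genes gave 2 and 0 of 12 (3 and 1; median 0.16, adjusted p = 0.0154), a call lost without wild-type replicate 2 (0.0593) and without cac3 replicate 1 (0.0615). Glycolysis genes gave 0 and 2 of 17 (1 and 5), ENO1 at -0.53 and TDH2 at -0.38 (median -0.07, adjusted p = 0.0357), a call lost without wild-type replicate 1 (0.105) and without cac3 replicate 2 (0.124). The CAF-I list, with MSI1 deleted, had a median of 0.01, a mean of -0.37 and a test pointing down (adjusted p = 0.0215), and its median was -0.06 without wild-type replicate 2 and -0.03 without cac3 replicate 1. The CAF-I call was lost without cac1 replicate 2 (0.0655), without cac2 replicate 2 (0.0645) and with wild type and cac3 alone in the fit (0.127). Among random lists matched on level glycolysis lay at percentile 41.03 in cac3, meiosis genes at 56.7, galactose genes at 66.3 and purine genes at 3.8, within the middle 95%. Without further scaling 2 cytosolic and 1 mitochondrial ribosomal protein genes fell and 5 phosphate genes rose, with medians of -0.05 for the cytosolic ones, -0.04 for glycolysis and -0.06 for purine genes. The block gave falls of 19 cytosolic and 7 mitochondrial ribosomal protein genes, 4 histone and 5 purine genes, and rises of 5 phosphate genes. In cac3 without wild-type replicate 2, 1 amino acid gene and 1 iron gene fell, 1 iron gene rose, and 0 genes of ribosomes, histones, purines, glycolysis, stress, meiosis, galactose, DNA damage or phosphate passed. The medians there were -0.05 for ribosomal protein, 0.13 for iron, 0.10 for DNA damage, 0.27 for stress and 0.35 for alpha-specific genes. Falls of 6 amino acid and 1 cytosolic ribosomal protein genes and rises of 2 iron, 1 stress and 3 meiosis genes (median 0.58) came without wild-type replicate 1. Without cac3 replicate 1, 4 amino acid genes fell and 2 iron, 1 phosphate and 1 meiosis genes rose, with 0 cytosolic ribosomal protein and 0 stress genes passing and an alpha-specific median of 0.96. Without cac3 replicate 2, 3 amino acid and 1 cytosolic ribosomal protein genes fell and 2 iron, 1 phosphate, 1 stress and 2 meiosis genes rose.

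In total 180 ORF-Ts rose and 95 fell in cac3 by edgeR, and 73 CUTs and SUTs rose and 71 fell. With replicate as a block there were 383 and 261 ORF-Ts with 174 and 157 CUTs and SUTs, and without further scaling 244 and 68 ORF-Ts (78.2% against 65.5% higher) with 94 and 52 CUTs and SUTs (64.4% against 50.7%). Without wild-type replicate 2 there were 11 and 5 ORF-Ts with 2 and 2 CUTs and SUTs, and 10 of the 16 features named by rule no longer passed, YNR064C then at 2.20 and SUT831 at 0.50. Without wild-type replicate 1 there were 101 and 43 ORF-Ts with 30 and 31 CUTs and SUTs; without cac3 replicate 1, 57 and 22 with 21 and 12; and without cac3 replicate 2, 69 and 30 with 21 and 25.

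Direct comparisons between mutants separated cac3 from the other two. FRE7 was higher by 2.41 (SE 0.09) in cac1 and by 2.84 (SE 0.09) in cac2 than in cac3, while PHO84 was lower by 2.41 (SE 0.10; edgeR adjusted p = 3.64e-07) and by 2.11 (SE 0.10). URA1 was lower in cac2 than in cac3 by 0.81 (SE 0.07), and CRR1, a gene of the spore wall, was higher by 1.22 (SE 0.16). CUT308 was higher by 1.69 (SE 0.27) and SUT837, divergent from YLH47, lower by 0.93 (SE 0.17) in cac1 than in cac3. Between cac1 and cac2 only 4 features passed: ARO10, the phenylpyruvate decarboxylase gene (0.65, SE 0.09), ALD6 for cytosolic aldehyde dehydrogenase (0.53, SE 0.07), and the deleted RLF2 and CAC2. The edgeR test called 4 features between cac1 and cac2, 99 between cac1 and cac3 (49 higher, 50 lower in cac1) and 44 between cac2 and cac3 (25 higher, 19 lower in cac2), and DESeq2 called 5, 96 and 47. For ORF-T windows on the opposite strand edgeR called 0, 1 and 0 in the same order, while DESeq2 called 0, 5 and 0. At an unadjusted p under 0.05 edgeR gave 41 and 341, 321 and 197, and 520 and 29 windows higher and lower. With replicate as a block the counts were 60, 618 and 188, and without further scaling the split of cac1 against cac3 became 83 and 33. Between cac1 and cac2, 2 features passed without wild-type replicate 1 or 2, cac1 replicate 1, or cac2 replicate 1 or 2, 3 without cac3 replicate 1 and 6 without cac1 replicate 2. ARO10 and ALD6 did not pass in those with 2. Between cac1 and cac3 there were 35 without wild-type replicate 1, 37 without wild-type replicate 2, 37 without cac1 replicate 1, 21 without cac3 replicate 1 and 17 without cac3 replicate 2. Between cac2 and cac3 there were 29 without wild-type replicate 2, 13 without cac2 replicate 2, 16 without cac3 replicate 1 and 20 without cac3 replicate 2.

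Whether noncoding transcription changed differently from coding transcription was asked with the CUT and SUT annotations. SUTs rose more often than they fell: 182 against 54 of 846 in the mean of the 3 mutants, 159 against 49 in cac1, 154 against 30 in cac2 and 55 against 24 in cac3. CUTs, which are degraded rapidly by the nuclear exosome, fell more often than they rose. In the mean 81 rose and 123 fell of 925, against 81 and 98 in cac1, 65 and 68 in cac2 and 18 and 47 in cac3. The SUTs rising most in the mean included SUT364 divergent from DBP5 (2.81, SE 0.53), SUT620 divergent from RPL17B (2.73, SE 0.61) and SUT801 (2.71, SE 0.25, edgeR adjusted p = 9.65e-05; chromosome XV, 1057511 to 1058463). With few wild-type reads SUT450, SUT561 and SUT649 were among them too. SUT041, which lies antisense on chromosome IV (59129 to 60697), fell from 15.5 ± 5.11 to 3.04 ± 1.10 in cac1, 3.31 ± 1.57 in cac2 and 4.39 ± 0.105 in cac3 (-2.09, SE 0.25). CUT743 divergent from YLR257W (-1.33, SE 0.30), CUT268 divergent from NEJ1 (-1.15, SE 0.13) and CUT049 divergent from WHI4 (-1.03, SE 0.12) were the others falling most. PPT1 and SUT129, a divergent pair, did not pass in any mutant and stood at 0.14 (adjusted p = 0.169) and -0.13 (adjusted p = 0.425) in the mean.

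The median log2 change of SUTs (n = 846) exceeded that of ORF-Ts by 0.21 in cac1 (camera p = 0.000242, and 0.0174 with the correlation estimated), 0.24 in cac2 (4.54e-06 and 0.0115), 0.08 in cac3 (0.0317 and 0.034) and 0.17 in the mean (0.000207 and 0.0242). None of the 4 passed with replicate as a block and the correlation estimated (camera p = 0.0691, 0.051, 0.108 and 0.0932, n = 846). Against as many ORF-Ts matched on level (n = 846) none of these calls held: the differences were 0.08 (camera p = 0.312), 0.13 (0.813), 0.02 (0.269) and 0.07 (0.513), with a test pointing down except in cac2. The cac3 call (n = 846) was also lost without further scaling (camera p = 0.15), with replicate as a block (0.0509), without wild-type replicate 2 (0.0963) and without cac3 replicate 2 (0.0713). CUTs (n = 925) differed from ORF-Ts by -0.06 in cac3 (camera p = 0.00932, and p = 0.288 with an estimated correlation), a call that ended without cac3 replicate 1 (-0.04, camera p = 0.101) and turned to 0.004 without wild-type replicate 2 (camera p = 0.218). In cac1 and in the mean the CUT differences (n = 925) of -0.06 and -0.04 did not pass (camera p = 0.133 and 0.136). They passed against ORF-Ts matched on level (0.0133 and 0.0136), without further scaling (0.00598 and 0.00895) and without wild-type replicate 1 (camera p = 0.0328 and 0.0205, n = 925), and in cac1 also without cac1 replicate 2 (0.0317). None of these passed with an estimated correlation: against matched ORF-Ts camera p = 0.269 and 0.276, without further scaling 0.179 and 0.178, without wild-type replicate 1 0.382 and 0.351, and without cac1 replicate 2 0.343 (n = 925). For CUTs in cac2 the difference was -0.002 (camera p = 0.748, n = 925). For all ncRNA together (n = 1771) the differences were 0.06 in cac1 (camera p = 0.334), 0.10 in cac2 (0.0422), -0.001 in cac3 (0.748) and 0.06 in the mean (0.323). The cac2 call (n = 1771) was lost with an estimated correlation (camera p = 0.16), without wild-type replicate 1 (0.103), without cac2 replicate 2 (0.113) and with replicate as a block (0.0501). It was also lost against ORF-Ts matched on level (0.58), where cac3 passed with -0.03 (0.0277, and p = 0.131 with an estimated correlation). Per library, the mean log2 level of SUTs relative to ORF-Ts was -1.40 ± 0.0072 in wild type (SD, n = 2) and -1.19 ± 0.0628 in the 6 mutant libraries, each above both wild-type libraries (exact two-sided permutation p = 0.0357, the smallest that the 28 splits allow). For CUTs the same values were -0.09 ± 0.0622 and -0.12 ± 0.0508 (exact permutation p = 0.571). Beside the wild type of the same replicate number, 5 of the 6 mutant libraries lay lower for CUTs and 0 for SUTs; the 16 exchanges within a number are too few for a test.

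**Figure D4:**
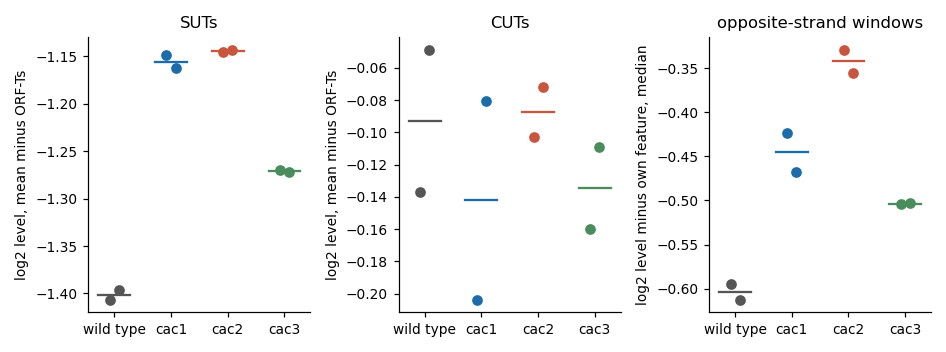
Level per library (points) and group mean (lines) of SUTs and CUTs relative to ORF-Ts, as differences of mean log2 level, and of the opposite-strand windows relative to their own features, as a median log2 ratio; axes do not start at 0. SUTs stood at -1.40 in wild type and at -1.16, -1.14 and -1.27 in cac1, cac2 and cac3.

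Divergent noncoding transcripts, which start upstream of an ORF-T on the other strand, fell more often than other ncRNA. They also had higher median log2 levels: 5.18 for SUTs and 6.15 for CUTs. Antisense transcripts had 4.50 and 5.43, and the others 4.69 and 5.64. Change depended on level, as given below, and the comparisons by position were not matched on it. An effect of level was thus not separated from one of position. Of 858 divergent CUTs and SUTs 12.1% rose and 13.3% fell in the mean of the 3 mutants, against 20.8% and 5.9% of 471 antisense ones and 13.8% and 7.9% of 442 others. In cac1 the counts were 91 and 96, 103 and 23, and 46 and 28; in cac2 98 and 59, 77 and 18, and 44 and 21; and in cac3 25 and 49, 31 and 10, and 17 and 12. The median of the divergent transcripts (n = 858) lay below that of the rest by 0.21 in cac1 (camera p = 0.000496), 0.15 in cac3 (0.000829, and by 0.09 without cac3 replicate 1) and 0.15 in the mean (0.0023). With an estimated correlation these did not pass (camera p = 0.121, 0.144 and 0.156, n = 858), but with replicate as a block as well they did (camera p = 0.0401, 0.0258 and 0.0447). In cac2 it lay 0.11 below and did not pass (camera p = 0.05, n = 858), but it passed without wild-type replicate 1 (0.0404), cac2 replicate 2 (0.0101), cac3 replicate 1 (0.0471) or cac3 replicate 2 (0.0481) and with scaling over all features (0.0457). In cac2 none of these passed with an estimated correlation (camera p = 0.363, 0.239, 0.205, 0.201 and 0.275, n = 858). Per library, the median log2 ratio of divergent transcript to partner was -0.51 ± 0.0463 in wild type (SD, n = 2) and -0.49 ± 0.0523 in the 6 mutant libraries (exact permutation p = 0.643). In 13 divergent pairs both members rose and in 26 both fell, against 11 pairs moving in opposite directions (9 and 2).

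Change depended on level in all 3 mutants. The 1818 features of lowest mean level (up to 33.0 RPKM) had a median of 0.20 in the mean of the mutants, with 457 rising and 35 falling, and the 1817 of highest level a median of -0.09, with 76 and 418. The lowest group had medians of 0.26 in cac1, 0.23 in cac2 and 0.13 in cac3.

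**Figure D5:**
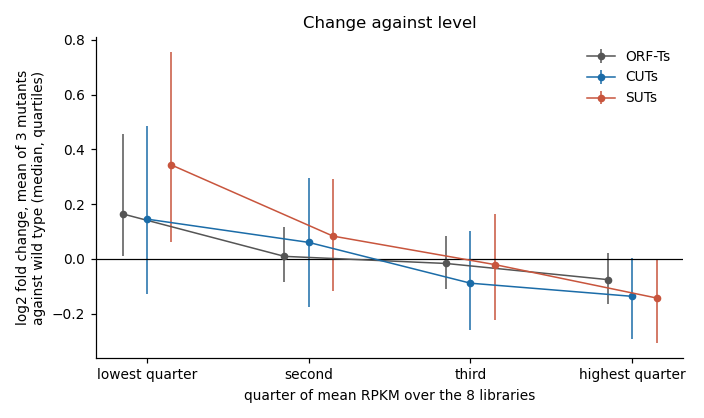
Median log2 fold change of the mean of the 3 mutants against wild type (points, with quartiles as bars) in 4 groups of features by mean RPKM, for ORF-Ts, CUTs and SUTs. In the group of lowest level the medians were 0.16, 0.15 and 0.34, and in the group of highest level -0.08, -0.14 and -0.14.

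Transcription opposite to promoters was read from windows at the 5′ ends of ORF-T-file features. Of 5165 windows 956 rose and 233 fell in the mean of the 3 mutants, 794 and 236 in cac1, 873 and 87 in cac2, and 285 and 45 in cac3. They were not matched on level, so its effect was not separated. The window of RPL26B rose from 26.2 RPKM in wild type to 117, 117 and 90.2 in cac1, cac2 and cac3 (1.91, SE 0.15, edgeR adjusted p = 1.32e-05) while the gene fell in the mean. That of ENO1 rose from 2.59 to 17.2, 17.7 and 11.4 (2.26, adjusted p = 0.000402), and ENO1 fell. The windows of DIT1 (2.31), GSC2 (1.87), GAL80 (1.37) and CWP1 (1.32) rose, and those of URA1 (-0.62), RPC10 (-0.54), URA4 (-0.42) and HTB2 (-0.31) fell. Singled out by size after their values were seen, the window of RPL22A rose from 2.15 RPKM (5 wild-type reads) to 31.1, 35.1 and 18.5, and that shared by ISC10 and SLO1 from 0.791 (4 wild-type reads) to 15.7, 16.7 and 10.4. The window of IME1 fell from 13.2 to 4.62, 3.66 and 7.04 (-1.25, SE 0.28), as did those of NEJ1 (-1.19) and WHI4 (-1.001), which hold CUT268 and CUT049. Most rising windows held no annotated transcript on their strand: 798 rose and 157 fell of 4122 in the mean. Of 919 with a CUT or SUT 145 rose and 70 fell, and of 124 with an ORF 13 and 6.

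The median window changed by 0.14 in cac1, 0.24 in cac2, 0.08 in cac3 and 0.15 in the mean, where 64.2% of windows were higher. Per library, the median log2 level of the windows relative to their own features was -0.60 ± 0.0126 in wild type (SD, n = 2) and -0.43 ± 0.0752 in the 6 mutant libraries, each above both wild-type libraries (exact permutation p = 0.0714). Without wild-type replicate 2 the windows past the threshold were 80 higher and 12 lower in the mean, 69 and 12 in cac1, 102 and 6 in cac2, and 2 and 0 in cac3. Without wild-type replicate 1 they were 709 and 111, 604 and 139, 731 and 52, and 179 and 16. Without cac1 replicate 1 there were 442 and 92 in cac1 and without cac1 replicate 2, 382 and 123; without cac2 replicate 1, 492 and 32 in cac2 and without cac2 replicate 2, 478 and 49. Without cac3 replicate 1 there were 81 and 1 in cac3 and 142 lower in the mean, and without cac3 replicate 2, 103 and 6 in cac3. With replicate as a block the windows were 1126 and 458 in cac1, 1232 and 189 in cac2, 608 and 171 in cac3 and 1286 and 405 in the mean. Without further scaling the lower ones were 147 in cac1 and 133 in the mean.

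CAF-I mutants are known for weakened silencing near telomeres, so the 143 ORF-Ts within 20 kb of a chromosome end were compared with the other 5028. In the mean of the 3 mutants 24 rose and 7 fell (16.8% rising against 10.4% of the others). Level was not matched, so the rise at low level was not separated from position. Singled out after being seen, the largest rises were on STL1 (2.33, SE 0.60), DMC1 (1.79) and YPS6 (1.47). YER187W (1.32), SEO1 (1.253) and YIR042C (1.20) followed. RPS4B (-0.31), YLR455W (-0.30), BAT2 (-0.28) and CHA1 (-0.25) fell. In cac1 24 rose and 4 fell, in cac2 20 and 4, and in cac3 12 and 1. The median of the subtelomeric ORF-Ts (n = 143) was above that of the others by 0.07 in cac1 (camera p = 0.00647), 0.07 in cac2 (0.00773) and 0.05 in the mean (0.0119). With an estimated correlation these did not pass (camera p = 0.137, 0.168 and 0.186, n = 143), though cac1 did with replicate as a block as well (0.0274). These calls were lost at a distance of 40 kb (n = 395, camera p = 0.0575, 0.0839 and 0.104) and in the mean without wild-type replicate 2 (0.0606). In cac3 the difference of 0.03 (n = 143) did not pass (camera p = 0.101) but passed without wild-type replicate 1 (0.0373), without cac3 replicate 2 (0.027) and at 10 kb (0.00588). These did not pass with an estimated correlation either (camera p = 0.324, 0.287 and 0.297, n = 143, and n = 57 at 10 kb). At 10 kb the difference was 0.15 in cac1, 0.13 in cac2 and 0.15 in the mean. It was 0.05 in cac1 without cac1 replicate 1 and 0.07 in the mean without cac2 replicate 2.

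Most features that changed in cac3 changed the same way in cac1 and cac2. Across all 3 mutants 231 features rose, 159 of them ORF-Ts and 63 CUTs or SUTs, and 120 fell, 63 of them ORF-Ts and 47 CUTs or SUTs; independent lists of these sizes would share 2.64 and 0.94. STE3, YHL012W, YNR064C, CAT2, GSY1, CTT1 and AGA1 rose in each, and MDH2, RIB4, URA1, CLB1, HTZ1 and HXT3 fell in each. Between cac1 and cac2 506 features rose in both and 303 fell in both (72.6 and 38.8 by independent lists), with 0 in opposite directions by edgeR. The cac1 mutant shared 239 and 131 with cac3 and cac2 shared 247 and 136, each pair with 4 in opposite directions. Across features the log2 changes correlated at 0.887 for cac1 and cac2, 0.849 for cac1 and cac3 and 0.868 for cac2 and cac3, where 30 simulations of unchanged groups against the same wild-type libraries gave means of 0.453, 0.508 and 0.506. Covariances were 0.183, 0.135 and 0.132 against simulated means of 0.0218, 0.0214 and 0.022. Because the comparisons share both wild-type libraries, each mutant of a pair was also compared with another wild-type library, after the data were seen. Part of the likeness can come from the shared controls. With no library shared the correlations were 0.59 and 0.613 for cac1 and cac2, 0.482 and 0.542 for cac1 and cac3, and 0.495 and 0.531 for cac2 and cac3.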

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

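Tests of depth, of the wild-type strain or libraries, of level in cac2 alone and of glucose exhaustion were chosen after the results were seen; the other tests in this part were written before the values they measure were seen.

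Differences between 2 mutants, tested directly by edgeR, singled out 11 genes or noncoding transcripts. FRE7 stood 2.41 higher in cac1 and 2.84 higher in cac2 than in cac3 on the log2 scale, and PHO84 at -2.41 and -2.11 (values 2.414, 2.841, -2.415 and -2.114). URA1 (-0.81) and CRR1 (1.22) separated cac2 from cac3, and CUT308 (1.69) and SUT837 (-0.93) separated cac1 from cac3. ARO10 (0.65) and ALD6 (0.53) separated cac1 from cac2. The deleted genes did so by construction: CAC2 at 1.85 in cac1 against cac2 and -1.64 in cac2 against cac3, RLF2 at -1.45 in cac1 against cac2 and -1.49 against cac3 (-1.445 and -1.485), and MSI1 at 1.27 in both cac1 and cac2 against cac3. SUT837 did not pass without either wild-type library, either cac1 library or either cac3 library, and CUT308 not without cac1 replicate 2 (1.20), cac3 replicate 1 or cac3 replicate 2. CRR1 did not pass without cac2 replicate 2 (1.17, edgeR adjusted p = 0.0931).

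Windows beside noncoding features entered no comparison of the report. In the mean of the 3 mutants 216 of 1774 were higher and 135 lower, with a median log2 change of -0.0067.

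Of the 1818 features of lowest level more rose than fell in the mean of the 3 mutants (457 and 35). An even background of reads added to the mutant libraries would raise such features alike. Their gains in replicates 1 and 2 correlated (at least 0.522 over the 3 mutants). Changes of some features would give this beside a background too, so the test cannot decide on it. A difference in depth is argued against by libraries thinned to one total: at least 18 more features were without a read in each wild-type library than in any mutant library. The wild-type strain or its libraries cannot be told apart from the deletions, since the median of the group of lowest level was positive in all 3 mutants (0.13 or more) against the same 2 wild-type libraries. A loosening of chromatin by loss of CAF-I, named by the design, stays open and untested.

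SUTs had a higher median change than ORF-Ts, and CUTs did not. Position as the whole cause is argued against in the mean of the 3 mutants, because SUTs exceeded CUTs within each of the divergent, antisense and other transcripts (by at least 0.18). In cac3 the difference was 0.13 for divergent transcripts and 0.07 for the others, where it did not pass (camera p = 0.142, n = 223 SUTs). A difference in level cannot be told apart: after matching 597 SUTs and 597 CUTs on level the difference in the mean of the 3 mutants was 0.10 (0.0977; camera p = 0.0209, and p = 0.123 with an estimated correlation, n = 597), against 0.21 before matching. Loss of CAF-I stays open beside it.

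In the mean of the 3 mutants 79 of 131 ribosomal protein genes fell and 12 of 23 stress genes rose (10 and 3 without wild-type replicate 2). The ribosomal protein median of -0.18 lay there at percentile 0.01 of random ORF-T lists of matched level (random median -0.13, in cac2 percentile 5.12). Such lists need not share these genes' correlation (0.168), so the ranking cannot decide on level. Without further scaling the median stayed at -0.12 and the falls went from 79 to 40. Leaving scaling out shifts all features of a library alike, by factors of only 0.962 to 1.02. This test therefore cannot decide on scaling as a cause. Mutant cultures nearer to glucose exhaustion at harvest could give this pattern and cannot be told apart: the glucose-repressed list lay at percentile 99.81 of matched lists but was chosen after its genes were seen, lay at 96.67 without wild-type replicate 2 and missed the threshold with an estimated correlation (camera p = 0.0811, n = 19). Loss of CAF-I stays open.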

How the results depend on the processing

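Alternatives on the windows and the deleted genes other than scaling, the fit of only the groups compared for classes, classes matched on level for CUTs and SUTs, the window relative to its own feature and separate wild-type libraries for 2 mutants were chosen after seeing the data. Over 63 results 653 of 855 values kept direction and side of the threshold (counts within 1.5 times), 27 lost and 16 gained the threshold, 158 counts or correlations moved and 1 difference reversed. Of 2788 values of named features 304 lost the threshold, 115 of them without wild-type replicate 2, and 0 reversed by edgeR or DESeq2. Leaving out the filter (0 of 54 values) or raising it to a mean RPKM of 5 (0 of 63) ended no call and moved no count by 1.5 times. The cause was not tested for the changes below unless stated; the lower counts without a library come with fewer samples. An alternative pseudocount was not run because counts were deposited. The pseudocount enters no edgeR or DESeq2 test. It does enter the per-library levels, their permutation tests and the matching of classes on level, and their dependence on it was not examined.

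DESeq2 called, higher and lower, ORF-Ts 269 and 207 in cac1, 223 and 157 in cac2, 87 and 50 in cac3, 279 and 210 in the mean. For CUTs and SUTs it called 114 and 69, 97 and 38, 28 and 22, 119 and 78, and for windows 223 and 57, 297 and 27, 45 and 3, 348 and 59. With the replicate block, in cac1: ORF-Ts 748 and 647, ncRNA lower 226, windows lower 458. In cac2: ORF-Ts lower 567, ncRNA 336 and 162, windows lower 189. In cac3: ORF-Ts 383 and 261, ncRNA 174 and 157, windows 608 and 171. In the mean: ORF-Ts lower 721, windows lower 405. Between mutants the block gave 60, 618 and 188. With it ncRNA in cac2 0.098 and SUTs in cac3 0.0781 lost. SUT450 in cac1, the subtelomeric families in cac1, cac2 and the mean and the sulfur list in cac1 lost their call, and the CAF-I list in cac2 gained one. With the block and an estimated correlation SUTs lost theirs and divergent in cac1, cac3 and the mean and subtelomeric in cac1 passed. The block changed no other call of the classes, lists and named features. Without further scaling: ORF-Ts 846 and 198 in cac1, 675 and 180 in cac2, 828 and 233 in the mean; windows lower 147 in cac1 and 133 in the mean. There ncRNA in cac2 (0.1013) and SUTs in cac3 (0.0826) lost the threshold and CUTs in cac1 (-0.053) and the mean (-0.0389) passed it. Features shared by cac1 and cac2 were then 793 higher and 157 lower, by cac1 and cac3 79 lower, by cac2 and cac3 85 lower. An estimated correlation ended ncRNA in cac2 (0.0995), CUTs in cac3 (-0.0629), divergent in cac1, cac3 and the mean (-0.2083, -0.1503, -0.1501), subtelomeric in cac1, cac2 and the mean (0.0743, 0.069, 0.0465), and all lists past the threshold (12, 12, 14 and 13 to 0 by camera). Against ORF-Ts matched on level ncRNA ended in cac2 (0.0541) and gained in cac3 (-0.0316), CUTs gained in cac1 (-0.0782) and the mean (-0.0534), and SUTs ended (0.0818, 0.1299, 0.0231, 0.0742). Scaling over all features made divergent in cac2 pass (-0.113) and only wild type and cac2 in the fit ended ncRNA in cac2 (0.1016). With a separate wild-type library for each mutant the correlations were 0.59 and 0.613 for cac1 and cac2, 0.482 and 0.542 for cac1 and cac3, and 0.495 and 0.531 for cac2 and cac3. The window relative to its own feature gave 26 lower in cac3, 10 kb made subtelomeric in cac3 pass (0.0894), and 40 kb ended cac1, cac2 and the mean (0.0443, 0.0318, 0.0308).

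Without each library in turn the ranges were, higher and lower, in cac1: ORF-Ts 103 to 501 and 66 to 447, ncRNA 32 to 224 and 23 to 149, windows 69 to 778 and 12 to 252. In cac2: ORF-Ts 90 to 456 and 56 to 369, ncRNA 32 to 232 and 19 to 109, windows 102 to 859 and 6 to 93. In cac3: ORF-Ts 11 to 186 and 5 to 110, ncRNA 2 to 70 and 2 to 78, windows 2 to 284 and 0 to 52. In the mean: ORF-Ts 75 to 564 and 61 to 513, ncRNA 29 to 242 and 23 to 181, windows 80 to 876 and 12 to 228. Between mutants they were 2 to 6, 17 to 120 and 13 to 48. Differences ranged over ncRNA in cac2 0.0951 to 0.1357, CUTs in cac1 -0.1048 to -0.002, in cac3 -0.1004 to 0.0041 (reversed without wild-type replicate 2) and in the mean -0.077 to 0.0219, SUTs in cac3 0.0743 to 0.0913, divergent in cac2 -0.1658 to -0.0597, subtelomeric in cac3 0.0004 to 0.0537 and in the mean 0.04 to 0.0708. The median of the CAF-I list in cac3 (0.0113) ranged from -0.0649, without wild-type replicate 2, to 0.0528, and was -0.0337 without cac3 replicate 1. Depth limits the features of few reads: fold changes of genes with 1 to 3 wild-type reads rest on their counting intervals.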

Other observations

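The lists of glucose-repressed genes and of fatty acid oxidation genes were added after the data were seen, as were the residual marker reads and the small RNA genes; the test of the alpha-specific genes was written before its value was seen, but that without wild-type replicate 2 after.

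Genes for growth on other carbon sources rose more often than they fell in the mean of the 3 mutants. Of 19 glucose-repressed genes 12 rose and 1 fell (median 0.82). SIP4 stood at 2.12, SFC1 at 1.90, JEN1 at 1.81, ADH2 and MLS1 at 1.35 each, and CAT8 at 1.16. Of 22 fatty acid oxidation and peroxisome genes 11 rose and none fell (median 0.31). POT1 rose by 3.13 with 7 wild-type reads and PEX18 by 2.79 with 4. SPS19 rose by 2.43, CRC1 by 2.01 and PXA1 by 1.73 on 1 of its 2 features. Among random lists matched on level the fatty acid list lay at percentile 66.7 (random median 0.25) and thus within them, against 99.81 for the glucose-repressed list, and 96.67 without wild-type replicate 2. With an estimated correlation neither list passed (camera p = 0.0811 for n = 19 glucose-repressed and 0.0602 for n = 22 fatty acid genes). Without wild-type replicate 2, 2 glucose-repressed genes rose and 1 fell, with a median of 0.47, and 1 fatty acid gene rose.

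Of 60 small nucleolar and small nuclear RNA genes 51 had a negative log2 change in the mean of the 3 mutants, with 21 falling and 1 rising. SNR33 (-0.61), SNR79 (-0.45), SNR49 (-0.42) and SNR67 (-0.41) fell and SNR128 (0.50) rose. Their median was -0.33 in cac1, -0.23 in cac2 and -0.13 in cac3. Level was not matched, so the fall at high level was not separated from this. The 3 most abundant small nuclear RNA features held 5.96% to 7.81% of the reads of each library. Whether small RNA reads were nascent or mature was not tested.

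Of 5 alpha-specific genes 3 rose in cells that also transcribed the a-specific receptor gene STE2. Whether this was the general rise of low-level features was tested against 10000 random lists of matched level: the alpha-specific median lay at percentile 100, but its median gene had 2 wild-type reads. Without wild-type replicate 2 the median was 0.38 and lay at percentile 59.85, inside the random lists, so the general rise cannot be told apart, and the bound set beforehand was wrong for a median that rests on 1 gene near the floor.

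The marker genes URA3, LEU2 and MET17 had few reads in each library. URA3 had 0 and 2 reads in wild type, 4 and 0 in cac1, 5 and 1 in cac2, and 6 and 1 in cac3; LEU2 had 4 and 1, 9 and 8, 6 and 4, and 15 and 6; MET17 had 4 and 1, 5 and 0, 4 and 0, and 10 and 1.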
